A study of Mus musculus with 4 samples.

How the data were processed

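Expression was measured in 3T3-L1 cells, a mouse embryonic fibroblast line that turns into fat cells when given insulin, dexamethasone and isobutylmethylxanthine. Per the labels, preadipocytes received a control siRNA (siGL3) or an siRNA against Aof2 or Rfk, were induced 24 h later, and were harvested 24 h after induction. In a further culture tranylcypromine was put into the induction medium, and the labels mention no siRNA for it. The medium held 25 mM glucose and 10% serum. Biotin-labelled cRNA was made from 250 ng of total RNA, and each of the 4 cultures went onto 1 Affymetrix 3' expression array with 45101 probe sets. The groups were taken from the labels, with 1 array per group. The control array's title ends in a 2, and whether this marks a further culture or array is not given in the sources used here.

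The deposited values are MAS5 signals, that is, a linear intensity per probe set computed by the authors from its perfect-match and mismatch probes, and MAS5 is named in the submitters' processing notes. Its version, the scaling target and the detection calls are not given in the sources used here. The mean signal without the lowest and highest 2% of probe sets was 500.003 on each of the 4 arrays, so the deposited intensities had been scaled array by array. The median signals were 53.3 (control siRNA), 56.2 (aof2 siRNA), 53.4 (rfk siRNA) and 55.6 (tranylcypromine). MAS5 sets no floor under dim probe sets, and their log2 differences scatter widely, so that the filter on signal decides how many genes pass a fold threshold. Equal trimmed means also hide any difference in total RNA per cell.

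Signals were taken to log2 with no offset. Gene names came from the platform annotation, in which 34958 probe sets had 1 gene symbol, 932 had several and 9211 were unnamed here. Of the 34958, the gene identifiers of 34754 were found in the RefSeq gene table of GRCm38.p6, which changed 0 symbols, and 204 kept the annotation's symbol. Probe sets with several symbols named no gene. Each of the 18194 named genes was represented by its probe set with the highest mean log2 signal over the 4 arrays, and 9012 genes had a choice between several. The 10788 genes whose mean log2 signal reached the median of all probe sets, a signal of 50.9, were compared. A gene was called higher or lower when its signals differed by at least 2-fold. Bright genes are the 6873 whose mean log2 signal reached the 75th percentile of the probe sets, a signal of 414. No coordinates are given, because the array design is not tied to a genome build in the sources used here.

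With 1 array per group no test between conditions is possible, and no p-value, SD or SE across cultures is given. Array and probe error was described instead from bacterial control transcripts, from probe sets of the same gene, and from 100 simulated draws of unchanged arrays. These draws took their spread either from all residuals of the 4 arrays, which include real differences, or from median absolute differences, which leave most of them out. The steps were tested on simulated data for aof2 siRNA against control siRNA over 10788 genes, with 50 genes altered at each size. The 2-fold threshold recovered 12% of genes altered 1.5-fold, 54% of those altered 2-fold, and 100% of those altered 4-fold or 8-fold, and 216 of 10588 unaltered genes passed it.

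Before the data were examined, 33 gene lists covering pathways, complexes and markers of other cell types were fixed. Of their 671 members, 613 were named on the array. For each of the 27 lists with at least 5 measured members, the median log2 difference was placed among the medians of 10000 random lists of the same size matched on mean signal in 20 bins. This percentile is a description of these arrays. Comparisons that share the control array were set against simulated unchanged arrays sharing it, and against differences that share no array. The control array could not be split.

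The rule for named genes was also fixed beforehand. It took the targeted genes, the 8 highest and 8 lowest log2 differences per comparison among genes whose brighter array reached a signal of 417, the 2 highest and 2 lowest members of each described list, Ppargc1a, Pdk4, Slc27a1 and Pnpla2, and the 5 genes higher and the 5 lower in all 3 comparisons whose smallest log2 difference was largest in size, with no bound on the dimmer signal. Other genes named below were chosen after their values were seen. The alternatives were centring on the median, quantile normalization, an offset before the log, no filter on signal, a stricter filter, the mean of all probe sets of a gene, leaving out probe sets that match several transcripts, the mean of the 3 other arrays as reference, and a 1.5-fold threshold. A further 2, a requirement that all probe sets of a gene agree in direction and a requirement that an array stand apart from all 3 others, were added after the data were seen. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.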

Results

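Genome-wide expression was compared between 4 cultures of differentiating 3T3-L1 cells, each measured on 1 array. The question was which genes depend on LSD1, a histone demethylase that uses flavin adenine dinucleotide and is encoded by Kdm1a (formerly Aof2), and which depend on riboflavin kinase, the enzyme encoded by Rfk that makes flavin mononucleotide. Tranylcypromine, an inhibitor of LSD1 and of monoamine oxidases, was the pharmacological counterpart. There were no replicates, so all values below are single measurements, and their number limits the precision. "Higher" and "lower" describe these arrays only.

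The targeted genes were low in the arrays labelled for their siRNA. Kdm1a had a signal of 3494 in the control siRNA array and 681 in the aof2 siRNA array, which is 19.5% of control, and a further probe set gave 17.3%. Its signal was 99.3% of control with rfk siRNA and 87.4% with tranylcypromine. Rfk had signals of 2122 in the control array and 573 with rfk siRNA, or 27.0% of control, and its other probe sets gave 30.6% and 39.7%. With aof2 siRNA Rfk was at 95.1% of control and with tranylcypromine at 110%.

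Technical spread was larger for dim transcripts than for bright ones. The 18 probe sets of the hybridisation controls differed from the control array by log2 values between -0.26 and 0.21. The 24 probe sets of the poly-A control transcripts, which are added to the RNA before labelling, differed by a mean of 0.29 in the aof2 siRNA array, 0.17 in the rfk siRNA array and -0.01 in the tranylcypromine array, with single probe sets as high as 0.87, 0.78 and 0.66. Log2 signals of all probe sets correlated between arrays with Pearson r of 0.932 to 0.938. The 3' over 5' signal ratio was 0.834 to 0.841 for Gapdh and 1.25 to 1.34 for beta-actin. In 5228 genes with several probe sets, their log2 differences lay apart by a median of 0.23, 0.23 and 0.27 for aof2 siRNA, rfk siRNA and tranylcypromine. In simulated unchanged arrays a mean of 111.54 genes per direction passed 2-fold by chance (range 89 to 137) with the wider spread and 55.38 (38 to 77) with the narrower. Among bright genes these means were 3.54 (0 to 9) and 0.27 (0 to 2). The draws have normal errors, and wider tails among dim genes would let more unchanged genes pass. A count above these ranges, here and below, therefore does not show an effect of the treatment.

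**Figure D1:**
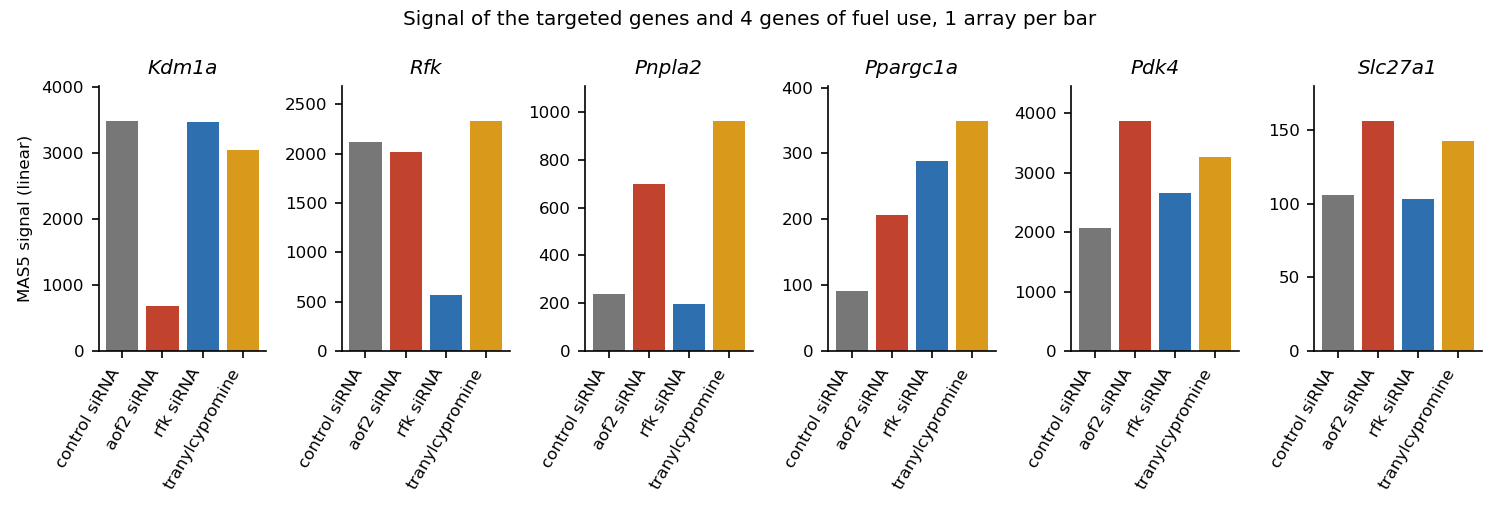
MAS5 signal on a linear scale (vertical axis) of Kdm1a, Rfk and 4 genes of fuel use in the 4 arrays, with 1 bar per array and no error bars because each group had 1 array. Kdm1a was at 19.5% of control with aof2 siRNA, Rfk at 27.0% with rfk siRNA, and Pnpla2 was 2.91-fold and 4.02-fold above control with aof2 siRNA and tranylcypromine.

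In cells with aof2 siRNA, inflammatory, cell cycle and glycolysis genes lay below control, and Fam107a, Tppp3, Slurp1 and Msln were among the genes reaching a signal of 417 that lay furthest above it. Fam107a, which encodes an actin-associated stress-response protein, was 10.3-fold higher, with signals of 200 and 2055 (its probe sets gave log2 differences of 2.28 to 3.36). The log2 difference was 2.74 for Tppp3, a tubulin-binding protein, 2.44 for Slurp1, a secreted protein, 2.15 for the aldehyde dehydrogenase Aldh1a7, and 2.13 for Msln, the surface glycoprotein mesothelin. Tesc (2.02), Crip1 (2.00) and Cystm1 (1.99) followed. Among genes reaching that signal, those furthest below control after Kdm1a itself included Rgs4, a regulator of G protein signalling, at -1.76, the chemokine gene Cxcl5 at -1.19, the circadian transcription factor gene Dbp at -1.12, Tmem63b at -1.11, Tmem98 at -1.07 and the prostaglandin receptor gene Ptgfr at -1.06. The probe sets of Rgs4 ranged from -1.76 to -0.62, and those of Tmem201, at -1.20, ranged up to 0.02.

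At least 2-fold above control were 174 of 10788 genes, and 58 were at least 2-fold below it, so that 75% of them were higher. With the arrays centred on their medians the split was 134 and 77, or 63.5% higher. This centring used all probe sets and moved the median log2 difference of the compared genes from -0.004 to -0.081. With quantile normalization, where that median was -0.009, the split was 153 and 67, or 69.5% higher. Among bright genes 38 were higher, above both simulated ranges for bright genes (0 to 9 and 0 to 2). The 7 lower bright genes lay within the wider of these ranges. The 174 higher genes exceeded what the simulated unchanged arrays gave with either spread, but the 134 of the centred arrays lay within the range of the wider one, and the 58 lower genes lay within the range of the narrower spread.

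Of the 27 lists, 8 had medians outside the central 95% of random lists in the aof2 siRNA array, against 1.35 for random lists. Random lists hold unrelated genes, whereas genes of a pathway can move together and some lists share members such as Fabp4. The 1.35 is therefore not the number that untreated cultures would give. All 28 measured S phase genes were below control, by a median of -0.22 (percentile 0), with 4 at least 1.5-fold lower, among them the replication licensing gene Cdc6 at -1.0 and the cyclin gene Ccne1 at -0.77. Of the 31 genes of G2 and M phase, 30 were below control, with a median of -0.31 (percentile 0). Their differences were small: 0 were at least 1.5-fold lower, Aurkb and Cenpe stood at -0.56, and Nusap1 at 0.59 was the exception above control. The 15 inflammatory chemokine and cytokine genes had a median of -0.38 (percentile 0), with 6 at least 1.5-fold lower, including Cxcl5, the acute phase gene Saa3 at -0.95 and Cxcl1 at -0.85, while Cxcl12 stood at 0.49. Against the mean of the 3 other arrays their median was -0.11. In the glycolysis list 13 of 15 genes were below control, with a median of -0.19 (percentile 0.06), led by Pfkfb3 at -0.82 and Pdk1 at -0.77.

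The 7 measured mature adipocyte markers had a median of -0.31 (percentile 0.37), with Fabp4, the fatty acid binding protein of fat cells, at -0.92 and Dgat2, an enzyme of triglyceride synthesis, at -0.84, and Agpat2 at 0.15. The 19 adipogenic transcription factors had a median of 0.22 (percentile 99.7), with Klf5 at 1.26 and Stat5b at 0.83, although the probe sets of Stat5b ranged from -0.30 to 0.83. The 17 glucocorticoid response genes had a median of 0.16 (percentile 99.8), with Pdk4 at 0.90 and Map3k6 at 0.72, and the 25 ribosomal protein genes one of 0.10 (percentile 97.6). The medians of mature adipocyte markers, adipogenic factors and ribosomal proteins came to lie within the central 95% under at least 1 other setting.

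**Figure D2:**
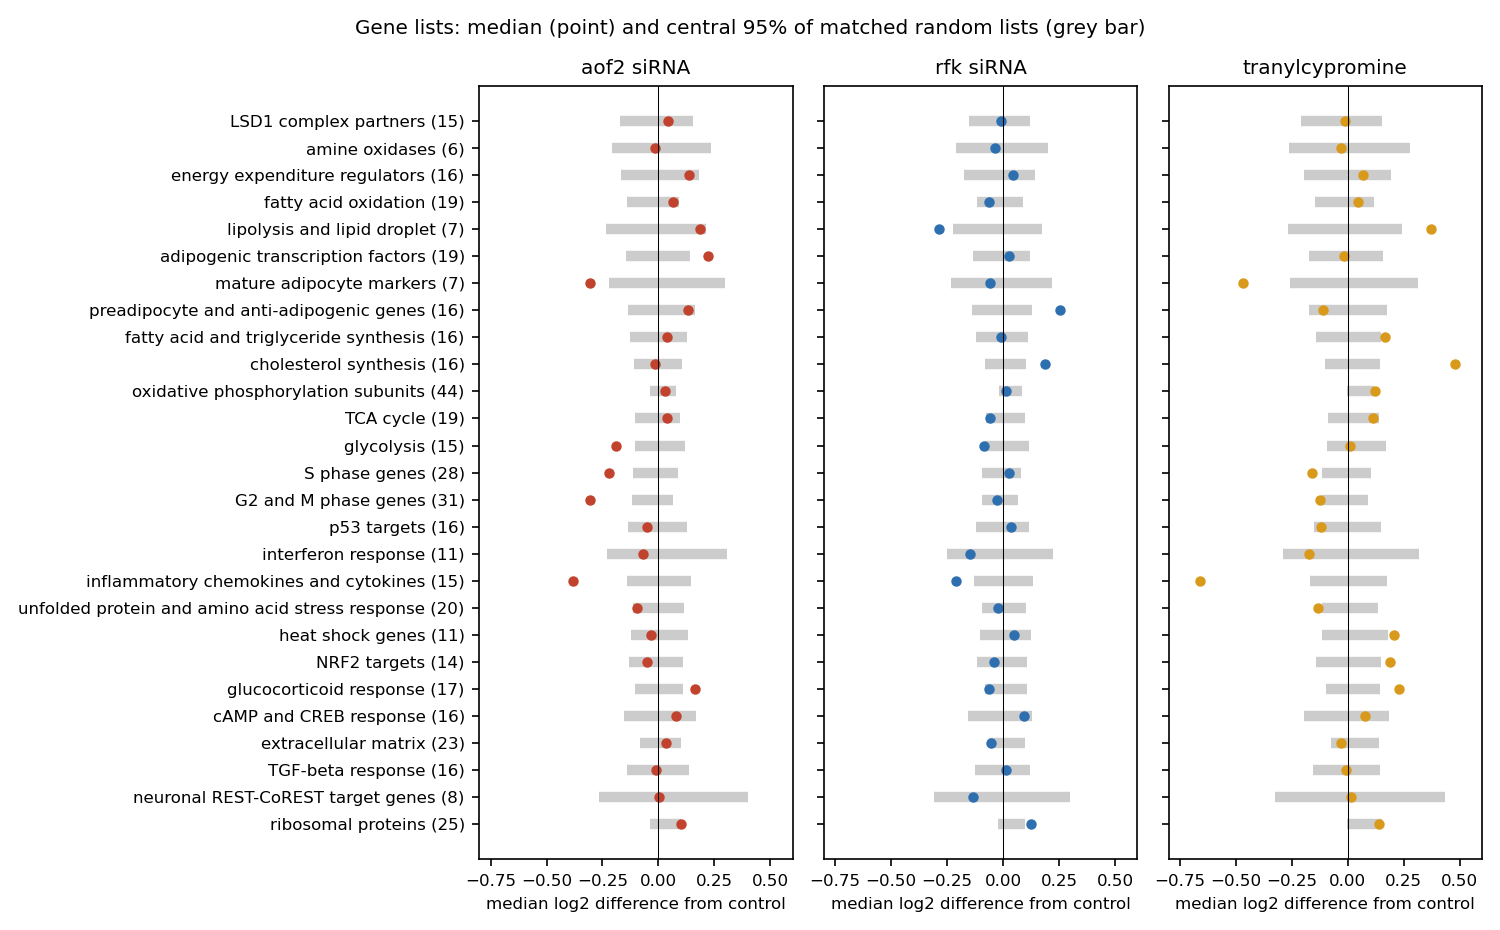
Median log2 difference from the control siRNA array (horizontal axis) of the 27 gene lists (vertical axis, number of measured members in brackets) for the 3 treated arrays, as points, with grey bars for the central 95% of 10000 matched random lists. Inflammatory genes lay left of the bar in all 3 arrays (-0.38, -0.21 and -0.66). The cell cycle lists lay further left with aof2 siRNA (-0.22 and -0.31) than in the other treated arrays, and cholesterol synthesis lay furthest right with tranylcypromine (0.48).

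Genes of fuel use were looked at separately because they are the known subject of the study. Ppargc1a encodes a coactivator of mitochondrial genes, Pdk4 a kinase that inhibits pyruvate dehydrogenase, Slc27a1 a fatty acid transporter and Pnpla2 adipose triglyceride lipase. Pnpla2 was 2.91-fold above control with aof2 siRNA and 4.02-fold with tranylcypromine, and at 0.82 of control with rfk siRNA, with signals of 240, 698, 197 and 963 in the control, aof2 siRNA, rfk siRNA and tranylcypromine arrays. Ppargc1a was above control in each treated array, by 1.18, 1.66 and 1.94 on the log2 scale for aof2 siRNA, rfk siRNA and tranylcypromine, from a low control signal of 91. Its 5 probe sets ranged from 0.41 to 1.28, from 0.81 to 1.66 and from 1.40 to 2.01. Against the mean of the 3 other arrays Ppargc1a with aof2 siRNA stood at -0.02. Pdk4 differed by 0.90, 0.36 and 0.65, and Slc27a1 by 0.56, -0.04 and 0.43. These 4 genes are not independent evidence of a direction, since they were taken from knowledge of the study.

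The 16 measured regulators of energy expenditure, which include these 4, had medians of 0.14, 0.04 and 0.07 for aof2 siRNA, rfk siRNA and tranylcypromine, within the central 95% of random lists (percentiles 93.3, 78.8 and 81.5), although with the stricter filter the aof2 siRNA median was 0.16, at its upper edge. Medians of the 19 fatty acid oxidation genes were 0.06, -0.06 and 0.05, also within it, but against the mean of the 3 other arrays theirs was -0.15 with rfk siRNA, below it. The 44 subunits of oxidative phosphorylation had medians of 0.03 and 0.01 with the siRNAs, and against that mean -0.05 with rfk siRNA, below it. With tranylcypromine theirs was 0.12 (percentile 97.9), with 37 genes above control and 0 at least 1.5-fold so, and it lay within the central 95% under 2 of the other settings.

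In cells with rfk siRNA, lipid droplet genes lay below control, while genes of preadipocytes and of cholesterol synthesis lay slightly above it. Fabp4 was lower by a log2 difference of -1.64, with signals of 2463 and 791, and its other probe set above the filter gave -1.51. Without probe sets that match several transcripts, Fabp4 rested on a dim one with a control signal of 26.6, which gave 0.33 with rfk siRNA and 0.57 with tranylcypromine, whereas a further dim one with a control signal of 31.8 gave -3.53 and -3.07, so these decide no direction. All 7 measured genes of lipolysis and the lipid droplet were below control, with a median of -0.29 (percentile 0.59; -0.60 against the mean of the 3 other arrays), and Plin4, which coats lipid droplets, stood at -1.06. Pparg, the nuclear receptor that drives adipogenesis, was at -0.77 and Dgat2 at -0.96, although the median of the 7 mature adipocyte markers was -0.06 (percentile 28.5). Of these markers 3 were above control, with Gpd1 at 0.91 from a control signal of 41.5, below the filter. The 19 adipogenic transcription factors, Pparg included, had a median of 0.03 (percentile 71.1), with 11 above control. Of 16 preadipocyte and anti-adipogenic genes 12 were above control, with a median of 0.25 (percentile 99.99), Sox9 at 0.71 and Wnt10a at 1.35, a difference of unreliable size because its control signal of 26.4 lay below the filter.

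Among genes reaching a signal of 417, those furthest above control with rfk siRNA were Fam107a (2.33), Aldh1a7 (1.86), the matricellular gene Ccn1 (1.78), Id4 (1.60), an inhibitor of helix-loop-helix factors, Abi3bp (1.47), the semaphorin gene Sema3c (1.44), Pkdcc (1.34) and Rnf7 (1.34). The probe sets of Ccn1 ranged from 0.22 to 1.78. Besides Rfk and Fabp4, those of this signal furthest below control were Fbxo42 (-2.0), Disp2 (-1.52), Nagk (-1.31), 1810058I24Rik (-1.25), the collagen-modifying enzyme gene Plod2 (-1.23) and Scarb1 (-1.23), the receptor for high-density lipoprotein. Other probe sets of Fbxo42, Nagk and 1810058I24Rik reached -0.17, -0.15 and 0.47.

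At least 2-fold above control were 100 genes with rfk siRNA and 87 were at least 2-fold below it, and neither number exceeded the range of the simulated unchanged arrays with the wider spread, while both exceeded that with the narrower. Among bright genes 23 were higher and 17 lower, both above the simulated ranges for bright genes (0 to 9 and 0 to 2). The limits given above for such draws hold here too. In the rfk siRNA array 6 lists lay outside the central 95%. Of 16 cholesterol synthesis genes 14 were above control, with a median of 0.19 (percentile 99.99), Dhcr7 at 0.90 and Insig1 at -0.69. The inflammatory list had a median of -0.21 (percentile 0.13), with Ccl7 at -0.85 and Ccl2 at -0.70. Glycolysis genes had a median of -0.09 (percentile 2.2) and ribosomal protein genes one of 0.13 (percentile 99.9). Apart from the preadipocyte list, each of these 6 came to lie within the central 95% under at least 1 other setting, and against the mean of the 3 other arrays the inflammatory and cholesterol medians were both 0.07. Against that mean the S phase and G2 and M phase lists had medians of 0.16 and 0.12 with rfk siRNA, above the central 95%.

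With tranylcypromine, cholesterol synthesis genes were above control and inflammatory genes below it. All 16 cholesterol synthesis genes were above control, with a median of 0.48 (percentile 100) and 3 at least 1.5-fold higher, namely Dhcr7 (1.14), Cyp51 (0.75) and Mvd (0.63), all enzymes of the pathway. Of the 15 inflammatory genes 13 were below control and 8 at least 1.5-fold so, with a median of -0.66 (percentile 0), Ptx3 at -1.08, Saa3 at -1.05 and Cxcl1 at -1.03, while Cxcl12 stood at 0.58. Against the mean of the 3 other arrays the inflammatory median was -0.35. The probe sets of Ptx3 ranged from -1.08 to -0.05. Msln was 11.1-fold higher, with signals of 194 and 2150, Slurp1 10.2-fold, Cystm1 8.35-fold, the proton pump subunit gene Atp6v0e2 7.49-fold, AU021092 7.38-fold and Scrn1 5.79-fold. Tesc (2.31) and Tppp3 (2.30) followed among genes reaching a signal of 417.

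Among genes reaching a signal of 417, those furthest below control with tranylcypromine were Gprin3 (-2.53), the glycogen-targeting phosphatase subunit gene Ppp1r3c (-2.03), the stress-inducible Sesn2 (-1.87), the nuclear non-coding RNA Malat1 (-1.84), the hyaluronan synthase gene Has2 (-1.81), the lubricin gene Prg4 (-1.79), the death receptor gene Fas (-1.68) and Rgs4 (-1.66). The 7 probe sets of Malat1 ranged from -2.89 to -0.12, those of Ppp1r3c from -2.03 to -0.93 and those of Sesn2 from -1.87 to -0.43.

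At least 2-fold above control were 241 genes with tranylcypromine and 102 were below it, so that 70.3% were higher. With the arrays centred on their medians the split was 203 and 132, or 60.6% higher. This centring moved the median log2 difference of the compared genes from -0.016 to -0.078. With quantile normalization, where that median was -0.009, the split was 241 and 107, or 69.3% higher. The 102 lower genes lay within the simulated range with the wider spread and above that with the narrower. Among bright genes 67 were higher and 21 lower, both above the simulated ranges for bright genes (0 to 9 and 0 to 2). In this array 12 lists lay outside the central 95%. The lipolysis list had a median of 0.37 (percentile 99.4), with 4 of its 7 genes above control and 3 below. Pnpla2, which was known from the study, stood at 2.01, Plin3 at 0.62 and Fabp4 at -1.17. The mature adipocyte list had a median of -0.47 (percentile 0.095), with Dgat2 at -0.85 and Retn at -1.10, of unreliable size because its signal of 37.8 lay below the filter. Of these 7 markers 3 were above control, Gpd1 and Fabp5 at 0.30 and Agpat2 at 0.08. Fatty acid and triglyceride synthesis had a median of 0.17 (percentile 98.5), with Scd1 at 0.62, Fasn and Acss2 at 0.61 and Thrsp at -0.88. The glucocorticoid list had a median of 0.23 (percentile 99.9), although its mean was 0.06, with Zbtb16 at -0.70 and Pdk4 at 0.65. Heat shock genes (0.21) and NRF2 targets (0.19) had medians above the central 95%. S phase genes (-0.16), genes of G2 and M phase (-0.12) and stress response genes of the unfolded protein type (-0.13) had medians below it. Against the mean of the 3 other arrays the mature adipocyte median was -0.25 and that of G2 and M phase -0.03. Only the cholesterol and inflammatory lists stayed outside the central 95% under every planned setting in which the list was described. The labels mention no siRNA for the tranylcypromine culture, so this comparison may also hold the difference between transfected and untransfected cells.

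The differences of aof2 siRNA and of tranylcypromine from control went together across genes. Pearson r over the 10788 genes was 0.65 and Spearman's rho 0.59, although genes are not independent replicates. For aof2 siRNA with rfk siRNA they were 0.47 and 0.39, and for rfk siRNA with tranylcypromine 0.37 and 0.32. Simulated unchanged arrays that share the control gave r of 0.50 (0.48 to 0.52) with the wider spread, which equal spreads in all arrays give by construction. The covariances were 0.102, 0.061 and 0.054 for these pairs, against 0.074 in the simulation. Only the pair of aof2 siRNA and tranylcypromine exceeded it. Between differences that share no array, aof2 siRNA minus control and tranylcypromine minus rfk siRNA, r was 0.26 and the covariance 0.042. For rfk siRNA minus control with aof2 siRNA minus tranylcypromine these were 0.056 and 0.0065.

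Genes higher in the aof2 siRNA and tranylcypromine arrays together numbered 96, where independent lists would share 3.89, and included Msln, Slurp1, Cystm1, Crip1, Krt19, Klf5 and Pnpla2. The aof2 siRNA and rfk siRNA arrays shared 49 higher genes (1.61 for independent lists), and rfk siRNA and tranylcypromine shared 43 (2.23). In each pair 34 of the shared higher genes were the same. In these the control array lay at least 2-fold below all 3 others, so low control signals alone could supply this part. Lower genes numbered 8 in each pair. Independent lists leave out the shared control array: simulated unchanged arrays that share it had a mean of 25.5 genes (14 to 39) past 2-fold in both with the wider spread and 10.64 (4 to 19) with the narrower. The shared higher genes exceeded both ranges in each pair and the 8 lower genes neither. The r of both pairs with rfk siRNA lay below the simulated one, which is set by equal spreads and is no measure of untreated cultures. The draws have normal errors, so wider tails among dim genes could raise the overlap, and an excess here does not show a shared effect. Of the 174 genes higher with aof2 siRNA, 117 (67.2%, Wilson 95% interval 59.96 to 73.8) had a higher signal with tranylcypromine than with rfk siRNA. Of the 241 genes higher with tranylcypromine, 188 (78.0%, 72.4 to 82.8) had a higher signal with aof2 siRNA than with rfk siRNA. For the lower genes the shares with a lower signal were 33 of 58 (56.9%, 44.1 to 68.8) and 56 of 102 (54.9%, 45.2 to 64.2), and both intervals hold an even split. An even split need not be the share of unchanged genes of like signal, which was not computed. Median signals over all probe sets were 56.2 with aof2 siRNA and 55.6 with tranylcypromine, against 53.4 with rfk siRNA. A difference in scaling among dim genes could thus enter these shares. Of the 100 genes higher with rfk siRNA, 60 (60%, 50.2 to 69.1) had a higher signal with aof2 siRNA than with tranylcypromine. Of its 87 lower genes, 40 (46.0%, 35.9 to 56.4) had a lower one. All these intervals treat genes as independent, which they are not.

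**Figure D3:**
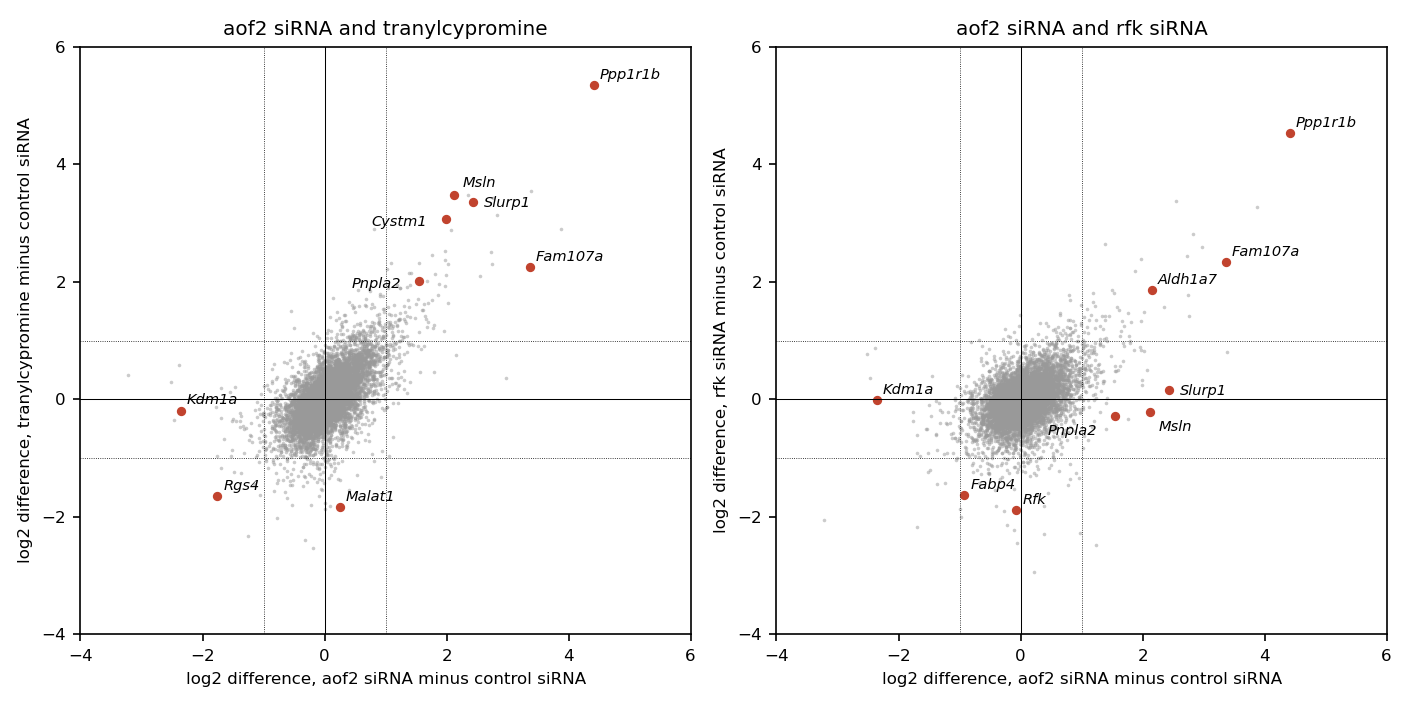
Log2 difference from control with aof2 siRNA (horizontal axes) against that with tranylcypromine (left panel) and rfk siRNA (right panel) for 10788 genes as grey points, with some named genes in red and dotted lines at 2-fold. Msln, Slurp1 and Pnpla2 lie far above control on both axes in the left panel, where r was 0.65, and near 0 on the rfk siRNA axis in the right panel, where r was 0.47.

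At least 2-fold above control in each of the 3 treated arrays were 34 genes, and 2 were at least 2-fold below it in each. Fam107a was among the 34. Ppp1r1b had a signal of 9.5 in the control array and 202, 221 and 387 with aof2 siRNA, rfk siRNA and tranylcypromine, Aldh1a1 one of 9.66 and then 142, 93.0 and 72.2, Ankrd13b one of 18.4 and then 131, 130 and 163, and Omp one of 14.7 and then 96.9, 79.5 and 83.3. Except for Fam107a these control signals were far below the filter's 50.9, so the sizes of the differences are unreliable. The 2 lower genes were the cytokine gene Il11 (-1.37, -1.44 and -1.26) and Vgf (-1.48, -1.20 and -1.23). Below control in each, but short of 2-fold in at least 1, were Aplp1 (-1.25, -0.93 and -2.34), Fabp4 (-0.92, -1.64 and -1.17) and Apobr (-1.51, -0.91 and -0.86). The treated signals of Vgf (41.4, 50.2 and 49.3), Apobr (38.6, 58.5 and 60.6) and, with tranylcypromine, Aplp1 (44.6) were near or below the filter as well. The other probe set of Aplp1, with a control signal of 7.58, gave 0.10 with tranylcypromine. For comparison, 37 genes were at least 2-fold lower in the rfk siRNA array, 38 in the tranylcypromine array and 11 in the aof2 siRNA array than in each of the others.

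Directly compared, tranylcypromine stood apart from aof2 siRNA in 73 higher and 104 lower genes. Besides Kdm1a, and among genes reaching a signal of 417 in the brighter array, the largest differences above aof2 siRNA were those of Zap70 (3.64, of unreliable size because its aof2 siRNA signal was 37.7, below the filter), Atp6v0e2 (2.09) and the filamin gene Flnc (2.05), and below it those of Malat1 (-2.09), Sesn2 (-1.88), Has2 (-1.58) and Aldh1a7 (-1.40). Between rfk siRNA and aof2 siRNA 61 genes were higher and 173 lower. Chst2 (1.69), Umps (1.31) and the proteoglycan gene Dcn (1.24) were higher with rfk siRNA, and Msln (-2.34), Slurp1 (-2.29), Orm3 (-2.22) and Pnpla2 (-1.83) were lower. Tranylcypromine against rfk siRNA gave 246 higher and 146 lower genes, led by Atp6v0e2 (4.0) and Msln (3.69) and by Malat1 (-2.05) and Sesn2 (-2.02). The rule of size used for the comparisons with control picked these genes, but its use here was decided after the values were seen.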

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

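Probe sets without a single gene name were used in no comparison above, yet some of them stood apart from the control array. Of the 2723 that passed the filter on signal, 55 were at least 2-fold above control with aof2 siRNA and 34 were at least 2-fold below it. With rfk siRNA 42 were above and 43 below. With tranylcypromine 60 were above and 59 below.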

How the results depend on the processing

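With 1 array per group no result has a replicate check, and no paired analysis was possible because each group held 1 array. Dim probe sets set the limit: without the filter on signal the genes at least 2-fold higher and lower numbered 2016 and 1502 for aof2 siRNA, 1809 and 1697 for rfk siRNA, and 2234 and 1557 for tranylcypromine, and with the stricter filter 38 and 7, 23 and 17, and 67 and 21. These counts differ by construction, since more or fewer dim genes were compared.

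At a 1.5-fold threshold the counts were 675 and 311 for aof2 siRNA, 423 and 410 for rfk siRNA, and 807 and 515 for tranylcypromine. With the mean of all probe sets the lower genes numbered 94, 149 and 199, and 56.0% were higher for tranylcypromine. Against the mean of the 3 other arrays 45 genes were higher and 29 lower for aof2 siRNA, 42 and 104 for rfk siRNA (28.8% higher, against 53.5%), and 104 and 80 for tranylcypromine (56.5%, against 70.3%). Apart from all 3 other arrays, a setting added after the data were seen, stood 5 higher and 11 lower genes for aof2 siRNA, 6 and 37 for rfk siRNA, and 24 and 38 for tranylcypromine. Kdm1a with aof2 siRNA was at -2.44 with centred arrays, -2.45 with the mean of its probe sets and -2.53 without probe sets matching several transcripts, and Rfk with rfk siRNA at -1.64 with the mean of its probe sets. Without the filter r was 0.52 for aof2 siRNA with tranylcypromine, 0.49 for aof2 siRNA with rfk siRNA and 0.48 for rfk siRNA with tranylcypromine, so the pairs hardly differed in this setting. Reversed in sign without probe sets matching several transcripts, where dim probe sets below the filter took their place, were Aplp1 with tranylcypromine (0.10) and Fabp4 with rfk siRNA (0.33) and tranylcypromine (0.57). Reversed against the mean of the 3 other arrays were Ppargc1a with aof2 siRNA (-0.0197) and the inflammatory list with rfk siRNA (0.0698), where the reference takes in the other treated arrays. For the other changes the cause was not tested. Of 26 list medians outside the central 95%, 26 stayed outside with centring, 25 with an offset, 22 with quantile normalization, 21 without the filter, and 18 with each of the mean of probe sets, the exclusion of probe sets and the other reference. With the stricter filter it was 22 of 24. The result with centring was fixed by construction and says nothing of stability. Centring shifts a list and its random lists alike, so no list median could cross the bounds of the central 95%. Newly outside came 0 medians with centring, 0 with an offset, 1 each with quantile normalization, no filter and the stricter filter, 2 with the exclusion, 6 with the mean of probe sets and 11 with the other reference. Among these, lipolysis with aof2 siRNA stood at 0.47 with the mean of probe sets and 0.26 with the other reference (0.18 in the main setting), and glucocorticoid response with rfk siRNA at -0.23 and -0.18 (-0.06). With the other reference cholesterol synthesis with aof2 siRNA stood at -0.20, fatty acid synthesis at -0.13 and unfolded protein response at -0.09. Ribosomal proteins with tranylcypromine stood at 0.14 without the filter and 0.15 with the mean of probe sets, and preadipocyte genes with aof2 siRNA at 0.14 with quantile normalization. Of 93 named gene values, 66 moved by over 0.5 on the log2 scale with the other reference, 20 with the mean of probe sets, 12 with an offset and 0 with quantile normalization. It was also 0 with centring and either filter setting, which says nothing of stability. Centring shifts all genes of an array alike, and a filter cannot alter the value of a gene. With the exclusion 11 of 88 moved that far, besides the 3 reversed.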

Other observations

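The 23 measured extracellular matrix genes had medians of 0.04, -0.05 and -0.03 for aof2 siRNA, rfk siRNA and tranylcypromine, within the central 95% of random lists, but single members stood apart. Against the mean of the 3 other arrays the aof2 siRNA median was 0.13, above it, and without probe sets matching several transcripts the rfk siRNA median was -0.12, below it. Timp3, an inhibitor of matrix proteases, stood at 1.11, 1.12 and 1.04, although its probe sets ranged from -0.24 to 1.11 with aof2 siRNA. The collagen gene Col1a1 stood at -0.55, -1.01 and -0.98, and Dcn at -0.18, 1.07 and -0.76. Among cAMP response genes, whose medians of 0.08, 0.09 and 0.08 also lay within the central 95% (but at 0.26 with aof2 siRNA and 0.31 with tranylcypromine above it with the mean of all probe sets), Gem stood at 0.95, 0.42 and 0.88, and Fos at 0.53, 1.17 and 0.11.

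Markers of other cell types were mostly below the filter on signal, with fewer than 5 measured per list and so no list median. Measured epithelial markers were Krt19 (1.41, 0.01 and 2.15 for aof2 siRNA, rfk siRNA and tranylcypromine), Epcam (0.50, 0.17 and 0.17) and Krt5 (-0.04, -0.05 and -0.08). Of the endothelial markers, Kdr stood at 1.0, 1.26 and 1.28 from a control signal of 29.0, and Flt1 at -0.15, 0.13 and -0.24. The macrophage marker Cd14 stood at 0.07, -0.72 and 0.48, and the muscle marker Des at -1.78 (with a dim aof2 siRNA signal of 25.7), 0.12 and -0.13. The cartilage marker Comp stood at 0.72, 0.75 and 0.19 from a control signal of 38.98. The 3 measured genes of flavin metabolism other than Rfk, namely Flad1, Slc25a32 and Blvrb, stayed within -0.37 and 0.19. The 8 neuronal targets of the REST and CoREST complex had medians of 0.00, -0.14 and 0.02, and the 15 partners of LSD1, Kdm1a included, had medians of 0.04, -0.01 and -0.01. Interferon response genes had medians of -0.07, -0.15 and -0.17. The lists with a median, and those of amine oxidases, the citric acid cycle, targets of p53 and the TGF-beta response, lay within the central 95% in all 3 arrays as processed for the comparisons above. With the mean of all probe sets the REST targets stood at -0.47 with aof2 siRNA, without probe sets matching several transcripts the p53 targets stood at -0.25 with tranylcypromine, and against the mean of the 3 other arrays the citric acid cycle stood at 0.13 with tranylcypromine, each outside it.

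Of the tests that follow, the correlations without a shared array and the one on the missing transfection were chosen only after the results were seen, and the mesothelial and progenitor marker lists were written after the genes furthest above control were seen. Between differences with no array in common r was 0.256 (bootstrap interval over genes 0.22 to 0.29). This restates that aof2 siRNA went more with tranylcypromine than with rfk siRNA. Its covariance of 0.042 is the 0.102 of the former pair less the 0.061 of the latter, so its sign followed from values already seen. The interval covers spread over genes and not over cultures. With 1 array per group this correlation therefore excludes no cause of the likeness of the aof2 siRNA and tranylcypromine arrays. That correlation replaced an earlier test on the share of 67.2%, whose lower bound of 59.96 just missed the bound set for it. Shifts of the median with signal contributed little to the r without a shared array: after the median of each of 20 signal bins was subtracted, it was 0.252 (0.22 to 0.28). This step removes no other kind of dependence on signal. The test set beforehand, r of 0.644 after the same step, shares the control array, for which arrays of equal spread give 0.50. A common action on LSD1 is a hypothesis for the likeness of the aof2 siRNA and tranylcypromine cultures, and it was not tested. A day or batch shared by these 2 cultures and not by the other 2 would give the same correlation, is not stated in the labels, and stays open.

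Inflammatory genes were below control with tranylcypromine and with aof2 siRNA. If the tranylcypromine cells were not transfected, a missing response to transfected RNA could lower these genes in that array, but this does not concern the aof2 siRNA culture, which per the labels was transfected like the control. For the tranylcypromine array the interferon list, which transfected RNA can raise, had a median at the 11.5th percentile (11.47), which decides nothing. A control array with unusually high inflammatory signals could also contribute. Against the mean of the 3 other arrays the medians were -0.11 for aof2 siRNA, 0.07 for rfk siRNA and -0.35 for tranylcypromine. That reference takes in the other treated arrays, so a high control and lower genes in all treated cultures would move these medians alike. They cannot tell these apart. Inhibition of LSD1 itself stays open as well.

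Msln, Slurp1, Krt15 and Krt19, which are made by mesothelial or other epithelial cells, were higher with tranylcypromine and aof2 siRNA, and Krt15 also with rfk siRNA (1.32). A candidate explanation is a share of mesothelial cells in these cultures. The labels give the same embryonic fibroblast line for each culture, so the design names no source of such cells. Among 11 further mesothelial markers only 2 were measured, Bnc1 (1.55 with tranylcypromine) and Igfbp6 (1.86), with a median of 1.71. This met the bound set beforehand for tranylcypromine, but the genes stood at only 0.47 and 0.55 with aof2 siRNA and Bnc1 at 0.66 with rfk siRNA, and 9 of the 11 lay below the filter, as did the keratins Krt8 and Krt18, whose signals were at most 49.8 in each array. Igfbp6 is also on the list of fibroblast progenitor markers, so a few induced genes cannot be told apart from a share of other cells on these markers.

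Pi16 (1.96 with aof2 siRNA, 0.88 with rfk siRNA and 1.17 with tranylcypromine) is, with Dpp4, a marker of fibroblast progenitors of adipose tissue, and Tppp3 is on the same marker list. A further hypothesis was that this marker set is higher as a whole, which may be a shift towards a progenitor state. The 8 measured markers not seen before had medians of 0.32 with aof2 siRNA (percentile 99.4), 0.20 with rfk siRNA (97.35) and 0.24 with tranylcypromine (96.45, short of the bound set beforehand). Furthest above control were Cd55 with aof2 siRNA (1.06), Igfbp5 with rfk siRNA (0.92) and Igfbp6 with tranylcypromine (1.86), while Igfbp5 stood at -0.63 with aof2 siRNA and Smpd3 at -1.08 with rfk siRNA, and Dpp4 itself was below the filter. The hypothesis was thus neither met nor excluded.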
